A study of Arabidopsis thaliana with 18 samples.

How the data were processed

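Gene expression in flowers of Arabidopsis thaliana was measured on Affymetrix ATH1 arrays, with 1 biotin-labelled cRNA sample per array. Plants were wild type (WT), an overexpressor of AtLEJ1 driven by the 35S promoter (OE), and a lej1 mutant (written KO as a group name). From each genotype, unopened buds of floral stages 1 to 12 and open flowers of stages 13 to 14 were collected from plants 5 weeks old, and 5 µg of total RNA was used, per the labels. This gives 6 groups of 3 arrays, 18 in all. Groups and replicate numbers come from the sample titles and source names. The free-text description of every sample reads as unopened wild-type flowers, which contradicts the titles of 15 of the 18 arrays, and it was not used. The labels call the 3 samples of a group biological replicates.

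The deposited table holds 1 linear intensity per probe set and array, for 22810 probe sets. The software and scaling behind these intensity values are not given in the sources used here. The trimmed mean (values between the 2nd and 98th percentile of each array) lay between 499.82 and 499.85 on every array, so each array had been scaled to 1 common level. Median intensity ran from 202 to 232, and the 40th percentile from 116 to 138. For arrays there is no count of reads, and their number limits the precision.

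From the deposited intensity values, log2(intensity + 16) was computed. Left out were 64 control probe sets, 1 probe set with an empty cell, and 7632 probe sets that were not above the 40th percentile of their own array on at least 3 arrays. The remaining 15113 were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 for the robust and random-effect fits), with 6 group means and 12 residual degrees of freedom, an intensity trend in the variance prior and Benjamini-Hochberg adjustment within each comparison. A probe set was called at an adjusted p under 0.05, and every adjusted p in the text is from limma unless camera is named. Fold changes are on the log2(intensity + 16) scale, which understates the change of dim probe sets. Errors of log2 changes are standard errors from the same fit, and SDs of intensities are over 3 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

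Gene names come from the platform annotation, matched by Entrez number to TAIR10.1 locus tags. It names 1 gene for 13513 probe sets and several genes for 503, and 8730 further probe sets apart from controls are unnamed here. Of the single-gene probe sets 13436 matched a locus tag, and 11933 carry only a locus tag as symbol. Of the tested probe sets 8204 name 1 gene. No coordinates are printed, since no source used here names a build for the array. No probe set in this annotation names LEJ1 (AT4G34120) or its nearest relative CBSX1 (AT4G36910), so the level of the targeted gene is not analysed here and the genotype labels were not checked with it.

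The named genes follow a rule set before the data were examined. In the genotype comparisons and the WT stage comparison these are the 10 largest rises and the 10 largest falls among called probe sets of 1 gene whose groups do not overlap, or all calls where there were fewer. In each interaction these are the 5 largest of each sign past the threshold, and where none passed, the 5 positive and 5 negative differences with the smallest p. From each list described, up to 4 members with the smallest p were taken. Other genes named in the text were chosen after their values were seen, and are said to be. Before the data were examined, 19 gene lists were also fixed. Of these 6 had at least 3 tested members. Tested were 6 of 28 for tapetum and pollen wall, 9 of 25 for mature pollen, 3 of 12 for floral terpene synthesis and 4 of 25 for jasmonate response. For photosynthesis and the Calvin cycle it was 4 of 19, and for the thioredoxin system 9 of 20. Members counted below are tested members only, so a list result does not speak for the members left out. These 6 lists were tested with camera (preset correlation 0.01, adjusted over the lists), with an estimated correlation and with fry as alternatives. Each gene was represented by its brightest single-gene probe set. A further 9 lists had 1 or 2 tested members and 4 had none.

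The replicate numbers in the titles run from 1 to 3 in every group. Same-numbered arrays deviated together from their group means: over all pairs of groups compared, the correlation of these deviations across probe sets (which are not independent) ran from 0.106 to 0.599. It lay above 0.1 for every pair, so the numbers were taken to pair the samples, on the evidence of the data and not of a label. For number 1 it ran from 0.318 to 0.599, and for numbers 2 and 3 from 0.106 to 0.390. Arrays of different numbers gave -0.488 to 0.356, which overlaps with both. With deviations taken from a mean of 3 arrays, a shift of replicate 1 alone can raise the values of numbers 2 and 3. The pairing of numbers 2 and 3 is thus not settled. The second principal component (7.57% of the variance) separated the 6 arrays of replicate 1 from the other 12. The fit without the replicate number stayed the main one, as fixed, and the fit with a replicate block is given beside results whose count of calls it moved by over 1.5 times. No array was identical to another in any of the 153 pairs. Within a group the correlation of log2 values across probe sets was 0.946 to 0.981.

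The procedure was tested on simulated data for the comparison of OE with WT in open flowers, with the real means and SDs of 15113 probe sets, of which 200 were changed. It recovered 30.0% of the changes of 1.5-fold, 74.0% of 2-fold, 96.0% of 4-fold and 98.0% of 8-fold, and 4.49% of its 156 calls were false. The simulated noise was normal and independent for each probe set and array. These rates therefore leave out the deviations that same-numbered arrays share, and may not hold for the real arrays. Alternatives were quantile normalization, centring of each array on its median, pseudocounts of 1 and 64, no filter and a 60th percentile filter, no intensity trend, a robust prior, array weights, a replicate block as a fixed or random effect (consensus correlation 0.192), a fit of the compared groups alone, a 2-fold minimum, and each array left out in turn. A fit of the 12 arrays of replicates 2 and 3, all alternatives for OE against KO, the leaving out of arrays for the gene lists, and the no-change values of OE and KO with residuals shared by same-numbered arrays (mean residual covariances over probe sets) were added after seeing the data.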

Results

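Transcript levels were measured in unopened buds (floral stages 1 to 12) and open flowers (stages 13 to 14) of 3 Arabidopsis genotypes: wild type (WT), plants expressing AtLEJ1 from the strong 35S promoter of cauliflower mosaic virus (OE), and a lej1 mutant (KO). LEJ1 is a protein built of CBS domains, and the series was set up to find transcriptional changes that AtLEJ1 induces. Each of the 6 groups held 3 arrays. Array medians lay between 202 and 232 intensity units, and 15113 probe sets were bright enough to test. The level of LEJ1 itself was not analysed here, because no probe set is named for it in the annotation used.

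**Figure D1:**
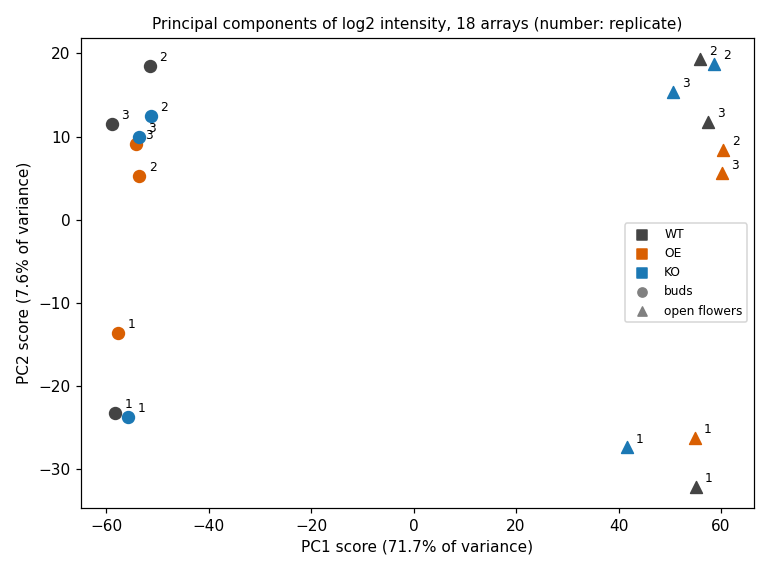
Scores of the 18 arrays on the first 2 principal components of log2 intensity (axes in score units, with the share of variance), coloured by genotype, with circles for buds, triangles for open flowers and the replicate number beside each point. The first component, with 71.7% of the variance, parts buds from open flowers, and on the second, with 7.57%, the arrays of replicate 1 lie at or below -13.6 and the others at or above 5.29.

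In the mutant, 1 probe set was lower than in WT at both stages. Probe set 253282_at, for which the annotation gives no gene, read 219 ± 11.2 (SD, n = 3) in KO buds against 2027 ± 160 in WT buds, and 320 ± 158 against 2940 ± 265 in open flowers. The log2 changes were -3.12 ± 0.21 (SE, adjusted p = 3.8e-07) and -3.23 ± 0.21 (adjusted p = 2.1e-07). In OE it differed from WT by 0.21 in buds and by -0.22 in open flowers, neither past the threshold (adjusted p = 0.999 and 0.807). Without a gene name, whether this probe set measures LEJ1 itself cannot be told here. It is thus not read as a gene that responds to LEJ1, and its levels were not used to check the genotype labels. The one other call was AT3G52870, which encodes a protein with an IQ calmodulin-binding motif. It rose in open KO flowers from 127 ± 35.4 to 796 ± 85.8 (log2 change 2.53 ± 0.17, adjusted p = 2.3e-07). In KO buds its log2 change was 0.96 ± 0.17, which did not pass (adjusted p = 0.154).

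Between KO and WT, limma thus called 1 probe set in buds, lower in KO, and 2 in open flowers, 1 higher and 1 lower. At an unadjusted p under 0.05 there were 429 probe sets in buds and 508 in open flowers, and 736 and 873 with a replicate block, where independent arrays without any change would give about 756. With a replicate block the count in open flowers was 5 (4 higher, 1 lower), and without the KO_open array of replicate 2 or the WT_open array of replicate 1 it was 8 and 4. In buds it was 2 without the KO_buds array of replicate 1 and 2 without the WT_buds array of replicate 2. The mean log2 ratio of 3' to 5' control probe sets, a measure of RNA integrity, was 0.240 ± 0.036 in KO buds against 0.377 ± 0.030 in WT buds and 0.261 ± 0.024 against 0.438 ± 0.012 in open flowers (SD, n = 3). OE lay below WT as well, at 0.306 ± 0.098 in buds and 0.371 ± 0.045 in open flowers.

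Among the fixed lists, none of the tested members of any list was called between KO and WT at either stage. In open flowers camera ranked 2 lists higher in KO: tapetum and pollen wall (6 members, median log2 change 0.52, adjusted p = 0.0050) and mature pollen (9 members, median 0.40, adjusted p = 0.0034). Both calls ended with an estimated correlation (adjusted p = 0.216 for each) and in the arrays of replicates 2 and 3 (adjusted p = 0.746 for each, medians 0.08 and 0.09), a fit chosen after seeing the data. Without the KO_open array of replicate 1 alone the medians were 0.10 and 0.19 (adjusted p = 0.761 and 0.643). The tapetum call also ended without the WT_open array of replicate 2 (adjusted p = 0.0690), and that of mature pollen without the WT_open array of replicate 1 (adjusted p = 0.0689). The tapetal lipid transfer protein gene A9 (AT5G07230) read 75.5 ± 58.0 against 7.09 ± 6.82, with all 6 arrays below the 40th percentile of their array. It had a log2 change of 1.71 ± 0.46 and was the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.0092), and the tapetal regulator AMS had 0.98 ± 0.38 (adjusted p = 0.0548 over the list alone). In buds no list passed camera, with adjusted p from 0.688 to 0.746. Of the smaller lists, salicylate and defence had 1 tested member, WRKY53, with a log2 change of 0.76 ± 0.22 in KO buds (unadjusted p = 0.0031, adjusted p = 1.00 over all probe sets).

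**Figure D2:**
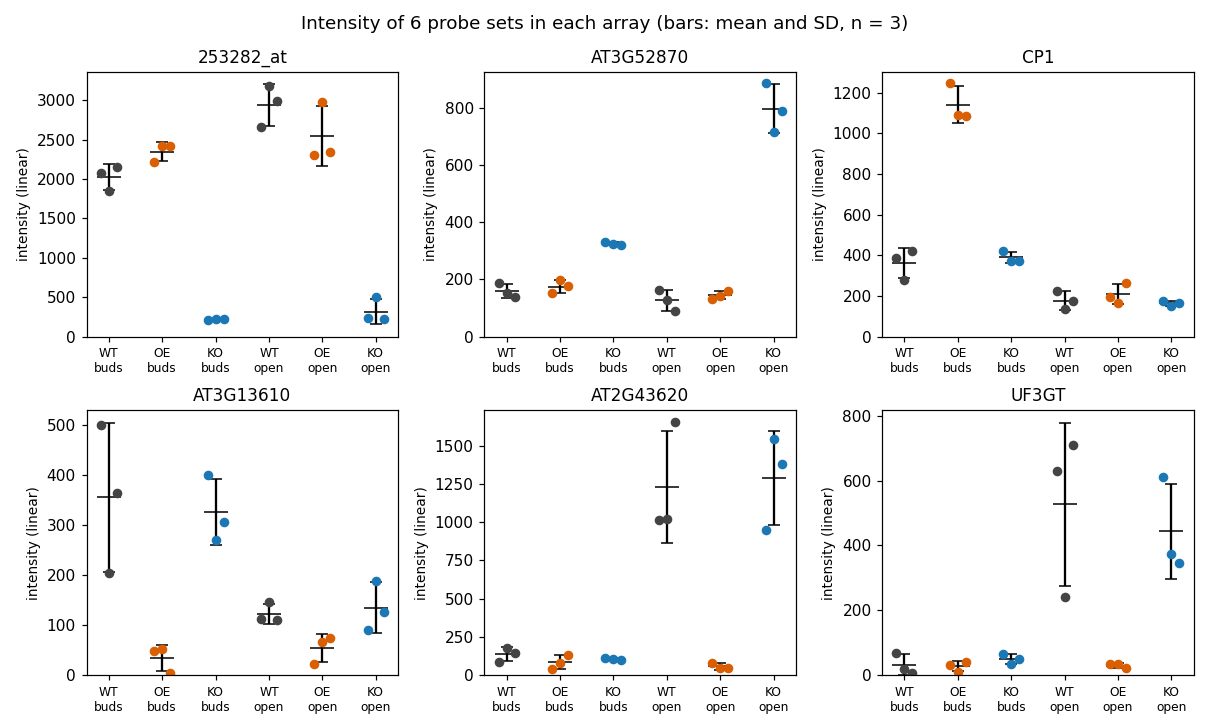
Linear intensity of 6 probe sets in each of the 18 arrays (points, 3 per group), with the mean and SD of each group as a dash and bar. 253282_at lies at or below 502 on every KO array and at or above 1846 on all others, AT3G52870 is at 714 or more on the KO arrays of open flowers, and AT2G43620 and UF3GT are low in OE open flowers, where their means are 57.2 and 29.3.

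In OE buds a small set of genes was lower than in WT. AT3G13610, which encodes feruloyl-CoA 6'-hydroxylase of coumarin synthesis, fell from 356 ± 149 in WT to 34.3 ± 25.9 (SD, n = 3; log2 change -2.99 ± 0.43, adjusted p = 0.0054). AT1G33700, of the GBA2 family of glucosidases, fell from 161 ± 19.9 to 17.1 ± 5.13 (-2.42 ± 0.33, adjusted p = 0.0043). AT1G05340 fell by 1.92 on the log2 scale, the metal transporter gene AT3G58060 by 1.63, the sucrose transporter gene SWEET13 (AT5G50800) by 1.37 and AT4G27435 by 1.26. The call of SWEET13 was lost in 12 of 19 alternatives, with a limma adjusted p of up to 0.206. CP1 (AT4G36880), a cysteine proteinase gene, rose from 361 ± 74.4 to 1142 ± 91.2 (1.64 ± 0.19, adjusted p = 0.0013). The subtilase gene AT5G59130 rose from 435 ± 18.3 to 828 ± 46.4 (0.90 ± 0.17, adjusted p = 0.0351), a call lost in 9 of 19 alternatives (limma adjusted p up to 0.201). These 8 are all the calls that name 1 gene, and of them only CP1 and AT4G27435 kept their call in every alternative.

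In all, 22 probe sets were called in OE buds, 3 higher and 19 lower. With a replicate block 71 were called (14 higher, 57 lower), and the arrays of replicates 2 and 3 alone, chosen after seeing the data, gave 10. The count was 9 without the WT_buds array of replicate 3, and 10 without that of replicate 1 or without the OE_buds array of replicate 1. No tested list member was called. Of the lists, mature pollen was ranked higher in OE buds by camera (9 members, median log2 change 0.24, adjusted p = 0.0098). That call ended with an estimated correlation (adjusted p = 0.519), and replicates 2 and 3 gave 0.0678. It also ended without the WT_buds array of replicate 1 or 3 (adjusted p = 0.0776 and 0.0835) or the OE_buds array of replicate 2 (adjusted p = 0.213). ANX2 and ANX1, receptor kinases of the pollen tube, had log2 changes of 0.81 ± 0.33 and 0.67 ± 0.33, and none of the 9 passed when adjusted over the list alone. The other lists had adjusted p from 0.900 to 0.968.

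In open flowers the falls in OE were larger and more numerous. The 2 chitinase-family genes AT2G43620 and AT2G43590 fell from 1231 ± 365 to 57.2 ± 21.1 (log2 change -4.09 ± 0.32, adjusted p = 1.1e-06) and from 544 ± 136 to 54.9 ± 19.0 (-2.99 ± 0.31, adjusted p = 3.7e-05). CHI, which the annotation places at the chitinase-family locus AT2G43570, fell by 2.54. Of genes of anthocyanin synthesis, UF3GT (AT5G54060), whose product adds xylose, fell from 527 ± 252 to 29.3 ± 7.75 (-3.46 ± 0.45, adjusted p = 6.4e-04), and AT4G14090, the anthocyanin 5-O-glucosyltransferase gene, fell from 160 ± 93.3 to 12.0 ± 13.6 (-2.55 ± 0.55, adjusted p = 0.0408). The call of AT4G14090 was lost in 8 of 18 alternatives, with an adjusted p of up to 0.216, without the WT_open array of replicate 3. AT4G15750, of the pectin methylesterase inhibitor family, fell from 3718 ± 2082 to 426 ± 162 (-2.96 ± 0.44), and the peroxidase gene AT5G64120 from 1415 ± 115 to 244 ± 45.7 (-2.47 ± 0.39). AT5G47350, AT3G49270 and AT1G65500 had log2 changes of -3.08, -2.40 and -2.01. The call of AT1G65500 was lost in 10 of 18 alternatives, with a limma adjusted p of up to 0.260.

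Rises in open OE flowers were smaller. AT4G07515 rose to 252 ± 79.0 (log2 change 2.38 ± 0.41, adjusted p = 0.0082). Among the genes selected by the rule, the peroxidase genes AT5G19880, AT4G11290 and AT3G03670 rose by 1.83, 1.75 and 1.49 on the log2 scale, while the peroxidase gene AT5G64120 fell. Peroxidase genes among the other calls were not counted. AT1G47470 and AT5G42955 each rose by 1.74, AT2G27180 by 1.28, GLC (AT1G65450), an acyltransferase gene, by 0.99, AT1G30795 by 0.98 and AT3G24100 by 0.97. Of these rises only those of AT4G11290 and AT2G27180 kept their call in every alternative. The calls of GLC, AT5G19880 and AT1G47470 were lost in 11 of 19, 9 of 19 and 8 of 18. For AT4G07515 and AT5G42955 all WT arrays of open flowers lay at or below the 40th percentile, so the size of their rises depends on the pseudocount. The full count was 103 probe sets, 27 higher and 76 lower, of which 52 name 1 gene, and 70 of the 103 changed at least 2-fold.

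Adding a replicate block gave 236 calls in open flowers (86 higher, 150 lower), and the arrays of replicates 2 and 3 alone gave 219. Centring each array on its median gave 36 higher and 62 lower. Without the OE_open array of replicate 2 or 3 the count was 41 or 56, and without the WT_open array of replicate 2 or 3 it was 68 or 43. Of the fixed lists 1 member passed, WRKY53 of salicylate and defence (AT4G23810, a transcription factor of leaf senescence), which fell by 1.34 from 203 ± 22.5 to 71.1 ± 13.5 (adjusted p = 0.0063). No list passed camera here, with adjusted p from 0.326 to 0.883. Of the jasmonate response list, THI2.1, a thionin gene, had a log2 change of 0.35 ± 0.11 and was the 1 of 4 members past the threshold when adjusted over the list alone (adjusted p = 0.0284). Over all probe sets its adjusted p was 0.248. In the smaller lists, OPCL1 of jasmonate synthesis (-0.53 ± 0.19, adjusted p = 0.0227) passed over the list alone. ADPG1, the 1 tested member of its list, had 0.69 ± 0.25 (unadjusted p = 0.0115, adjusted p = 0.295 over all probe sets).

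**Figure D3:**
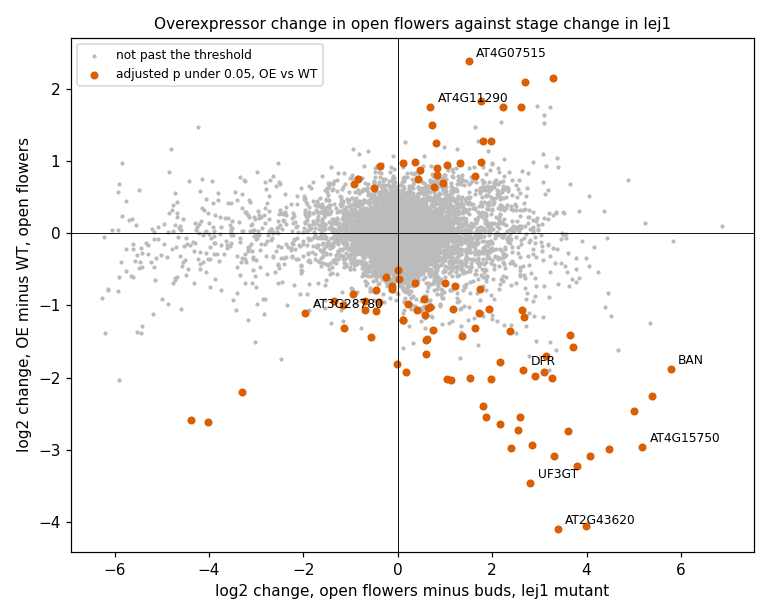
Log2 change between OE and WT in open flowers (vertical axis) against the log2 change from buds to open flowers in KO (horizontal axis) for the 15113 tested probe sets, with the 103 called between OE and WT in orange. Of the 76 lower ones, 46 were called higher in open flowers than in buds of KO, and of the 27 higher ones, 19.

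From buds to open flowers of WT, genes of the tapetum, the inner lining of the anther, fell. Among the large falls was that of A9 (AT5G07230), from 4327 ± 259 to 7.09 ± 6.82 (SD, n = 3; log2 change -7.59 ± 0.46, adjusted p = 1.3e-09), a level below the filter in open flowers, so that its size depends on the pseudocount. The lipid transfer protein genes AT5G62080 and AT3G52130 had log2 changes of -7.55 and -6.93, LCR66, for a small cysteine-rich protein, -7.42, and the tapetal gene ATA27 -7.42. AT1G68875, AT1G47980, AT1G02813, AT1G33430 and AT2G03740 lay between -7.35 and -6.54. The peroxidase gene AT2G37130 rose to 2504 ± 1232 (5.67 ± 0.57, adjusted p = 4.4e-07). The pectin methylesterase inhibitor family genes AT1G56100 and AT4G15750 each rose by 5.63, the former from 14.6 ± 20.5 to 1495 ± 840. BAN, for anthocyanidin reductase, rose by 5.58 from 4.96 ± 2.67 to 1085 ± 536. CYP71B31 rose by 5.38, AT5G39520 by 5.37, the aspartyl protease gene AT5G10770 by 4.66, AT5G64120 by 4.64, AT3G24510 by 4.49 and the carboxylesterase gene AT1G68620 by 4.42.

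In the tapetum and pollen wall list 5 of the 6 tested members fell in WT and 1, the receptor kinase gene EMS1, was not called (0.33 ± 0.20). SHT, AMS and SPL had log2 changes of -6.33, -5.41 and -3.63, the list median was -5.43, and camera gave an adjusted p of 1.5e-06 (0.0428 with an estimated correlation). All 5 also passed when adjusted over the list alone. All 3 tested members of floral terpene synthesis, out of 12 listed, rose, CYP71B31 by 5.38, TPS24 by 2.60 and TPS11 by 0.95 (camera adjusted p = 0.0030, and 0.143 with an estimated correlation). CYP71B31 spread widely, at 32.0 ± 37.0 in buds and 2355 ± 2509 in open flowers (SD, n = 3), so the size of its rise is uncertain, while its call held in all 19 alternatives. Mature pollen genes went both ways: ANX2 and TUA1 rose by 2.45 and 1.30, SWEET5 and AGL104 had changes of -4.66 and -1.67, with 2 higher and 4 lower of 9 over all probe sets and 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.490). In the jasmonate response list THI2.1 rose by 1.24 and MYC4 by 0.94, and 2 of 4 members passed both over all probe sets and over the list alone (camera adjusted p = 0.174). None of the 9 tested thioredoxin system members (of 20 listed) and none of the 4 tested photosynthesis members (of 19) was called (median log2 changes -0.15 and -0.06, camera adjusted p = 0.526 and 0.835). Of the 14 tested members of the 9 smaller lists, 3 rose (PRX52, WRKY53 and AIM1, by 4.04, 1.44 and 0.67) and 3 fell (RBOHE, ADPG1 and SPT, at -2.62, -1.31 and -0.57), and over the list alone ZAT10 passed too (0.91 ± 0.42, adjusted p = 0.0445).

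In WT 3529 probe sets were called between the stages, 1859 higher and 1670 lower in open flowers. In KO there were 3160 (1679 higher, 1481 lower) and in OE 4704 (2154 higher, 2550 lower). The OE split turned with arrays centred on their medians (2643 higher, 1813 lower) and with quantile normalization (2343 higher, 2151 lower). Of the calls in WT, 2728 were also called in KO, all in the same direction, and 2768 were also called in OE, 2761 in the same direction. Independent lists of these sizes would share about 370 and 547 in the same direction. In OE the tapetum and pollen wall list again had 5 of 6 members lower (median -5.85, camera adjusted p = 4.4e-06, and 0.0540 with an estimated correlation), and in KO too (median -4.75, camera adjusted p = 1.0e-06, and 0.0391).

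The stage change itself differed between OE and WT for 27 probe sets, 7 with a positive and 20 with a negative difference (stage change in OE minus that in WT). AT2G43590, UF3GT and AT2G43620 rose in WT and were not called between the stages of OE, with differences of -3.64 ± 0.43 (adjusted p = 5.4e-04), -3.46 ± 0.64 (adjusted p = 0.0315) and -3.42 ± 0.45 (adjusted p = 0.0014) on the log2 scale. Probe sets 265091_s_at, listed for 2 genes, and 262119_s_at, which is unnamed here, gave -4.34 ± 0.60 and -3.09 ± 0.35. The 5 largest positive differences were of probe sets that fell in WT and were not called between the stages of OE. AT1G33700 gave 2.46 ± 0.47 and AT3G58060 1.90 ± 0.37 (adjusted p = 0.0374 and 0.0426), with 251297_at, 250120_at and 249070_at, unnamed here, at 2.04, 1.85 and 1.82. In open flowers of WT and OE, AT1G33700 and AT3G58060 lay at or below the 40th percentile on all arrays, so no further fall in OE could show there. The same holds in buds for AT2G43590, UF3GT and 265091_s_at. The calls of UF3GT, AT1G33700 and AT3G58060 in this interaction were lost in 13 of 25, 13 of 24 and 14 of 24 alternatives (adjusted p up to 0.118, 0.390 and 0.137). No fixed list passed camera (adjusted p from 0.612 to 0.788). In the smaller lists PRX52 (-1.02 ± 0.41, adjusted p = 0.0477) and OPCL1 (-0.65 ± 0.26, adjusted p = 0.0494) passed over the list alone and not over all probe sets, and WRKY53, the 1 tested member of its list, had -1.14 ± 0.31 (unadjusted p = 0.0020).

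With a replicate block 109 probe sets were called in this interaction (31 positive, 78 negative), quantile normalization gave 9 positive and 15 negative, and centring 12 and 15. The count was 44 in replicates 2 and 3, and 45 without the WT_open array of replicate 1. It was 13 without the WT_open array of replicate 3, the OE_open array of replicate 1 or the OE_buds array of replicate 2, 12 without the OE_buds array of replicate 3, and 16 without the OE_open array of replicate 2. For KO against WT, limma called 0 probe sets in the interaction (1 without the WT_open array of replicate 1 or the KO_open array of replicate 2), and 145 had an unadjusted p under 0.05 (293 with a replicate block). The smallest p was that of AT3G52870 (1.57 ± 0.24, adjusted p = 0.0876). The next by p among positive differences did not pass either (adjusted p = 1.00 each): AT5G13380 at 1.55, AT5G64870 at 0.88, AT2G05160 at 1.19 and AT3G07450 at 1.40. Among negative ones these were AT4G33380 at -0.98, nad9 at -0.88, OASA2 at -1.10, AT3G11230 at -0.48 and AT5G39520 at -0.93. The tapetum and pollen wall list was ranked higher (median 0.59, camera adjusted p = 0.0049), but not with an estimated correlation (adjusted p = 0.344) or in replicates 2 and 3 (median 0.15, adjusted p = 0.845). It was not called either without the KO_open array of replicate 1 (median 0.16, adjusted p = 0.437), the WT_buds array of replicate 1 (adjusted p = 0.105), the WT_open array of replicate 2 (adjusted p = 0.0656) or the KO_buds array of replicate 2 (adjusted p = 0.0566).

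Set against each other directly, OE and KO differed in many of the genes already named. Probe set 253282_at was higher in OE than in KO by 3.33 in buds and 3.01 in open flowers. In open flowers AT2G43620, AT5G47350 and UF3GT had log2 changes of -4.17, -3.33 and -3.31 between OE and KO, AT3G52870 had -2.33, and the peroxidase genes AT4G11290 and AT5G19880 were higher in OE by 2.49 and 2.37. In buds AT3G13610 had -2.93 and CP1 was higher by 1.51. In all, 31 probe sets differed in buds (4 higher and 27 lower in OE) and 230 in open flowers (57 higher and 173 lower). Of the probe sets called in OE against WT, 20 of 22 in buds and 82 of 103 in open flowers were called here as well. Both comparisons use the same OE arrays, which favours such sharing.

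The changes in OE and in KO relative to the shared WT arrays correlated across probe sets with r = 0.485 in buds and 0.101 in open flowers, where unchanged groups of independent arrays simulated against shared controls gave 0.500 in both. The covariances were 0.0234 and 0.0065, against 0.0285 and 0.0286 simulated. With the residuals shared by same-numbered arrays taken into account, no change would give r of 0.474 and 0.526 and covariances of 0.0167 and 0.0210. The count of probe sets called both in OE and in KO against WT was 0 at each stage, where independent lists of these sizes would share 0.0015 in buds and 0.014 in open flowers. The WT arrays are too few to split. In the direct comparison, a replicate block gave 61 calls in buds and 827 in open flowers, and replicates 2 and 3 gave 11 and 372. In buds its count was 11 and 16 without the OE_buds array of replicate 1 or 2, and 9 and 10 without the KO_buds array of replicate 1 or 3. In open flowers it was 143, 145 and 101 without the OE_open array of replicate 1, 2 or 3, and 79 without the KO_open array of replicate 3. Quantile normalization gave 59 higher and 95 lower in open flowers, and centring gave 171 higher and 116 lower, so that the larger side turned.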

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

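The test of the stage score and that of the size of the falls after quantile normalization were chosen after the result was seen. The tests of replicate 1, of the number of calls after quantile normalization and of other splits of the arrays were set before.

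The effect of overexpression differed between buds and open flowers for 27 probe sets, by the interaction term in limma. Those that name 1 gene are 13. The stage change in OE minus that in WT was negative for AT2G43590 (-3.64 on the log2 scale), UF3GT (-3.46), AT2G43620 (-3.42), BAN (-2.94), AT3G49270 (-2.52), AT3G10720 (-2.36), AT2G47550 (-1.66), AT3G28780 (-1.58) and CP1 (-1.42). It was positive for CES (1.02), AT4G27435 (1.65), AT3G58060 (1.90) and AT1G33700 (2.46). For AT3G58060 and AT1G33700 in open flowers, and for AT2G43590, UF3GT, BAN, AT3G49270 and 265091_s_at in buds, all WT and OE arrays lay at or below the 40th percentile, so a fall in OE could not show at that stage. AT3G10720 and AT2G47550 are pectin methylesterase genes and CES is a bHLH transcription factor gene. Of the 14 without a single gene name, the 5 selected by the rule were 265091_s_at (-4.34), 262119_s_at (-3.09), 249070_at (1.82), 250120_at (1.85) and 251297_at (2.04). Of 100 splits of the 12 arrays, keeping the stages, 1 (the real one) gave as many calls as 27, and the highest of the others gave 21, in a split that keeps the genotypes of open flowers apart and mixes those of buds. For KO the real count was 0, which all 100 splits must reach, so that these splits decide nothing about chance. The highest split there gave 47. It puts both replicate 1 arrays of open flowers on one side and both replicate 1 arrays of buds on the other, which points to the structure of replicates. With a replicate block the real count was 0 as well.

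For the comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real count was reached by 1 split, the real one, in OE buds (22, highest other 0), OE open flowers (103, highest other 5) and the stage comparisons of WT, OE and KO (3529, 4704 and 3160, highest other 0 in each). In KO buds 2 splits reached the real count of 1 (highest other 1). In KO open flowers 2 splits reached the real count of 2, and the highest other gave 7. That split puts the arrays of replicate 1 of both genotypes together and parts 1 pair of same-numbered arrays, while the real split parts 3. Among the 3 other splits that part 3 pairs, the highest count was 1 in KO open flowers, 1 in KO buds and 0 in the remaining comparisons.

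Of the 76 probe sets lower in OE open flowers, 46 (60.5%) rise from buds to open flowers in KO, against 11.1% of all tested probe sets (Fisher's exact test, two-sided, p = 3.2e-25, over probe sets, which are not independent). So do 19 of the 27 higher ones (70.4%), so the rise is not particular to the lower ones. A change in open flowers can be called only where open flowers have signal, which favours probe sets that rise with stage. All tested probe sets are thus an unequal background for this p. A stage score was taken as the mean of 1679 rising less that of 1481 falling probe sets called in KO. It differed by -0.0198 ± 0.0412 (SE) between OE and WT open flowers (1.67 ± 0.07 and 1.69 ± 0.01, SD, n = 3). The lower calls that rise in KO lacked a median of 81.2% of their rise. A lag of that share in all scored probe sets would need a difference of -2.43. The score thus argues only against a harvest so early that OE open flowers were close to buds. It cannot decide on a slightly earlier harvest among open flowers, since it is built from the change between buds and open flowers. A lag of some late genes alone stays open as well. The 162 probe sets that rise in KO by at least the median of those lower calls (2.57) had a median OE change of -0.20. Unless removed, the lower calls that rise by this much are among the 162 by definition, so these are not a set apart from the lower calls. Most of the 162 did not lack 81.2% of their rise, while 37.0% were lower by well over that median OE change. In replicates 2 and 3, 100% of the 76 keep their direction at an unadjusted p under 0.05, so the falls do not rest on replicate 1 alone. That share cannot say more, since the 76 were called with these same arrays. The groups of OE and WT did not overlap in any of the 103 calls, which fixes the direction. Scaling as the source of the size of the falls is argued against by the log2 change after quantile normalization, a median of 93.9% of that before. Past the threshold stay 69.7% (53 of 76), which by itself does not decide. The falls themselves may come from overexpression of LEJ1, or from pollination, position on the plant or seed lots, none of which was tested.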

How the results depend on the processing

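The alternatives for OE against KO and the fit of replicates 2 and 3 were added after seeing the data. No gene selected by the rule changed sign. The larger side of the calls between stages of OE turned with centring (2643 higher, 1813 lower) and with quantile normalization (2343 higher, 2151 lower), and centring also turned that of OE against KO in open flowers (171 higher, 116 lower). The cause of a moved count was not tested, except that a 2-fold minimum and a left-out array can only use fewer probe sets or samples. With a replicate block as a fixed effect the counts were 71 (OE buds), 236 (OE open flowers), 5 (KO open flowers), 109 (OE interaction), and 61 and 827 (OE against KO, buds and open flowers); as a random effect 60, 221, 4, 97, 52 and 671, with 2 in KO buds and 1 in the KO interaction. The fixed block moved no other count by over 1.5 times and changed the call of no gene list. Array weights gave 40, 263, 2 (KO buds), 5, 116 and 1 (KO interaction), and 725 for OE against KO in open flowers. Replicates 2 and 3 gave 10, 219, 4, 44, 11 and 372 in the order of the fixed block. The 60th percentile filter gave 11 and 64 in OE buds and open flowers and 18 for OE against KO in buds. No filter gave 13 in OE buds and 4 in KO open flowers. A pseudocount of 1 gave 13 in OE buds; 64 gave 53 in the OE interaction, 2 in KO buds and 1 in the KO interaction. Centring gave 2 in KO buds, no intensity trend 2 there, and a robust prior 42 in the OE interaction. The compared groups alone gave 14 in OE buds and 130 for OE against KO in open flowers. At 2-fold or more the stage counts were 1786 (WT), 1908 (OE) and 1653 (KO), and OE against KO in open flowers gave 122. Leaving out 1 array at a time gave 9 to 25 (OE buds), 41 to 106 (OE open flowers), 1 to 2 and 2 to 8 (KO), 2887 to 3186, 3812 to 4153 and 2613 to 2813 (stage in WT, OE and KO), 12 to 45 and 0 to 1 (interactions), and 9 to 24 and 79 to 220 (OE against KO).

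Of the genes selected by the rule, all 20 of the WT stage comparison and all 3 calls in KO passed the threshold under every alternative run. In OE 2 of 8 in buds, 9 of 20 in open flowers and 3 of 10 in the interaction did so. SWEET13 and GLC, for example, had adjusted p up to 0.206 and 0.259. The alternatives planned for the level of LEJ1 were not run, since no probe set is named for it here. For arrays, signal over background sets the limit: many of the lowest values, such as A9 in open flowers, lie below the filter, and their fold changes depend on the pseudocount.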

Other observations

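The test of neighbouring genes was chosen after the grouped genes had been seen, as were the gene blocks and the pathway list, and so was the comparison of 3' to 5' ratios within groups, while the other tests of replicate 1 were set before.

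Several genes of flavonoid and anthocyanin synthesis were lower in OE open flowers. Of 26 genes of the pathway 6 were tested through a named probe set, and 4 of these fell: UF3GT had a log2 change of -3.46, AT4G14090 -2.55, DFR, the reductase of dihydroflavonols, -1.89 (limma, adjusted p = 0.0032) and BAN, the reductase of anthocyanidins, -1.88 (adjusted p = 0.0083). UGT78D2 and CHIL had changes of -0.60 and -0.49, not past the threshold (adjusted p = 0.253 and 0.747). In WT these same 4 genes rose from buds to open flowers and UGT78D2 and CHIL fell, and KO gave the same counts of 4 higher and 2 lower. In OE 1 of the 6 rose, BAN, and with a replicate block DFR did too (adjusted p = 0.0426 against 0.0709 without). None of the 6 was called in KO against WT at either stage. The difference in stage change between OE and WT passed for 2, BAN and UF3GT (lost in 13 of 25 alternatives), and had an adjusted p of 0.0533 for DFR (0.0184 with a replicate block) and 0.413 for AT4G14090, whose fall in OE open flowers was itself lost in 8 of 18 alternatives.

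Of the 35 genes with a locus tag that were lower in OE open flowers, 7 lay near others of them in the genome. They form 9 pairs within 10 protein-coding genes of each other, against a mean of 0.473 and a highest of 5 in 10000 random sets of tested genes (one-sided permutation p = 0.0001, the smallest these can give). That is more pairs than in any random set. The test was run on the genes in which the grouping was noticed, so its p cannot decide on chance placement. The pairs fall in 2 blocks, AT2G43570 to AT2G43620 and AT3G28780 to AT3G28830, and in the first 4 of 4 tested chitinase-family genes fell in OE, with log2 changes of -2.54, -2.99, -1.13 and -4.09, and all 4 rose with stage in WT and in KO. Around the second, 7 genes from AT3G28750 to AT3G28980 were listed after the calls were seen, and 6 of them were tested. The list leaves out most genes of that stretch, since AT3G28980 lies 25 protein-coding genes beyond AT3G28830. Of the 6, 4 fell in OE: AT3G28780, AT3G28790 and AT3G28830 (-1.10, -0.94 and -0.78) and AT3G28980 (adjusted p = 0.0222). AT3G28840 (-0.49, adjusted p = 0.611) and AT3G28750 (0.62, adjusted p = 0.139) were not called. With stage in WT, 5 of the 6 fell. Neighbours that arose by duplication may share regulation, or their transcripts may bind each other's probes; neither was tested.

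The arrays of replicate 1 stood apart from those of replicates 2 and 3 in every group: 3926 probe sets differed (limma, adjusted p under 0.05), 1886 higher and 2040 lower in replicate 1. The 3' to 5' ratio of actin, GAPDH and ubiquitin controls differed by -0.0537 on the log2 scale (0.296 ± 0.088 in 6 arrays against 0.350 ± 0.077 in 12, SD; two-sided permutation p over all 18564 choices = 0.199), a test that ignores how the groups differ. Within groups, the array of replicate 1 had the lowest mean ratio of these controls in all 6 (two-sided permutation p over all 729 choices of 1 array per group = 0.0096). The controls did not go together: in every group but OE buds, replicate 1 had the highest GAPDH ratio of its group. A difference in RNA integrity is thus not settled, and whether it accounts for the probe sets was not tested. Scaling is argued against, since 3963 probe sets differed after quantile normalization. A difference of growth, harvest or hybridization day stays open and was not tested, and no biological explanation was tested.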
